A study of Mus musculus with 16 samples.

How the data were processed

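RNA was sequenced from GFP-positive haematopoietic stem cells of young (12 weeks) and aged (over 80 weeks) mice after lentiviral transduction (multiplicity of infection 30, 16 h) and culture in medium with 10% serum at 3% oxygen. Per the labels' protocols, cDNA came from a low-input template-switching kit and libraries from a tagmentation kit, which do not mark the strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. Groups and replicate numbers were taken from the sample titles, 4 libraries in each of 4 groups.

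The authors deposited 1 table of estimated counts, which need not be whole, for 55471 genes in 16 libraries. Per the submitters' processing notes the build was GRCm38; the aligner and the counter are not given in the sources used here. How reads shared by near-identical genes were divided is therefore not known, and members of multigene families such as ribosomal protein, metallothionein and interferon-induced genes are uncertain to that extent. Exons of another annotated gene overlap those of Bax, Bin1, Bmpr1a, Cd37, Cd9, Cdc20, Cdk4, Engase, Fdft1, Fpgs, Gipc2, Hspa8, Ikbke, Junb, Mpo, mt-Co1, Pdia3, Rpl4, Satb1, Sbspon, Scrn1, Tc2n, Trf, Vcp and Xist, among the genes named in the report, so their counts may hold reads of both. Symbols were found for 55144 of the gene identifiers, 55230 identifiers were in GENCODE M21 and 54937 had the same start and end there. No row lacked a gene name, and 0 columns of sample values were left unused.

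In the deposited table, 12144 estimated counts had been turned into dates by a spreadsheet, 0.86 to 2.05% of the genes in each library. No plain decimal number was left in the ranges that a spreadsheet reads as dates, so each date was read back as the decimal number its day, month or year stand for; the largest such value was 31.12. All 16 columns were a mixture of counts and dates, with 476 to 1135 such cells each, over 1% of the genes in 11 of them. All were decoded before use, and an alternative took the cells as 0. Counts were rounded to whole numbers for the tests. Total counts per library were 31199413 to 101659592.

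Genes were kept by filterByExpr of edgeR, which left 18313, and scaled by TMM factors. The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) over all 16 libraries with group means and no block, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were OE against control within each age, aged against young within each vector, the OE effect averaged over both ages and its difference between ages. The average of the age effect over both vectors was added after the results of the other comparisons were seen. CPM are counts on the usual scale of edgeR, relative to the TMM-scaled library total, and errors are SDs between 4 libraries unless given as SE of a log2 fold change. For a gene at 0 in all libraries of a group, the fold was computed against a floor of 3 counts per library and is given as a bound. With 1 to 3 counts on the lower side, the ratio is given with its 95% counting interval. Both cover counting error only. Single values were compared with exact two-sided permutation tests.

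Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over 32 lists within each comparison. The lists, written from general knowledge and not from these libraries, were genes higher in aged stem cells (HSC ageing list), HSC and stemness markers, and megakaryocyte and platelet, myeloid and granulocyte, erythroid and mast cell and basophil genes. Others were lymphoid priming, mature B and T cells, monocyte and macrophage, and endothelium and stroma. Cell cycle and protein quality were covered by G1/S and DNA replication, G2/M and mitosis, proteasome subunits, ubiquitin E1, E2 and cullin-RING, ER-associated degradation, ER chaperones and unfolded protein response, ATF4 and integrated stress response, heat shock and cytosolic chaperones, and autophagy and lysosome. The rest were p53 targets and senescence, interferon response, NF-kB and inflammatory, immediate early and handling stress, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, polarity and Rho GTPases, cytokine receptor and JAK-STAT targets, Polycomb with DNA methylation and chromatin, cytosolic ribosomal proteins, mitochondrially encoded genes, and sex-linked genes. Some genes are in more than 1 list, such as Cd9 and Vwf in the ageing and the megakaryocyte list, so their results are not independent. Each list was also tested with an estimated correlation and with fry. A list score is the mean log2 CPM of the measured members with a prior count of 2.

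Named genes were chosen by a rule. In each comparison with calls it names Ube2g1 and, per direction, up to 8 passing genes with the largest change, at least 5 CPM in the higher group and all libraries of one group beyond the other, leaving out gene models without a proper symbol and pseudogenes. Of each list with a call or at least 3 passing members it takes up to 4 passing members, and of a list with no passing member up to 2 with the highest mean CPM, given as values. Where fewer than 5 genes pass, the 5 with the smallest p are given as not passing, again leaving out gene models without a proper symbol. Genes outside the rule are said to have been chosen after their values were seen. The groups, tests, lists, this rule and 99 alternatives were fixed before the data were examined, and 62 alternatives were added later. The alternatives were DESeq2 1.42.0, limma-voom with sample weights, RLE scaling, no filter or a stricter filter (1 CPM in 4 libraries) and the replicate number as a block. Others were fits of the compared groups only, leaving out each library, leaving out both young libraries numbered 3, thinning to the smallest library, date cells as 0 and the number of detected genes as a covariate.

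The tests were checked on simulated counts of the same genes with 200 genes changed. In young OE against control (17541 genes tested) edgeR recovered 4.48% of 2-fold, 44.8% of 4-fold and 63.6% of 8-fold changes, and in aged OE against control (17504 genes) 4.48%, 35.8% and 54.5%. In aged against young it recovered 7.46%, 33.3% and 62.1% with the control vector (17503 genes) and 4.55%, 48.5% and 67.7% with the OE vector (17515 genes). In these 4 sets it also called 78, 0, 15 and 19 unchanged genes. For the same folds limma-voom recovered 1.49%, 19.4% and 25.8% in young OE against control and 28.4%, 67.2% and 83.3% in aged OE against control. It called 4 and 20 unchanged genes there. A further 20 simulated sets with no change held each gene at its mean over all 16 libraries. They kept the spread of each age, estimated over both vectors, which is wider in young libraries. In these edgeR gave an unadjusted p under 0.05 to 13.4% of genes in young OE against control and to 0.811% in aged OE against control, since the groups share 1 estimate of the spread, and called 8.90 and 0 genes on average. In the same sets camera called on average 6.95, 6.75 and 10.6 lists in the comparisons of age with the control vector, with the OE vector and averaged, against 0.05 to 0.25 in the comparisons of vectors. With an estimated correlation it called 4.85, 4.25 and 8.35 lists for age, so that test too is inflated by the uneven spread. The simulated genes vary independently, so these counts can be too low for genes that vary together. Other groupings of the real libraries gave up to 15 lists for OE in young cells, 10 in aged cells, 17 for the difference and 13 for OE averaged. DESeq2 called 1081 unchanged genes in the simulated sets of young OE, 19 of aged OE, 397 and 405 of age with the control and OE vector, 297 of the difference and 312 of OE averaged, so its counts are given only beside those of edgeR. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 142 to 1112 over genes with at least 50 counts). Scripts ran in Python 3.11.15 and R.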

Results

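Long-term haematopoietic stem cells, the bone marrow cells from which all blood lineages can be rebuilt, were sorted from young (12 weeks) and aged (over 80 weeks) C57BL6 mice, an inbred laboratory strain. The cells were exposed for 16 h to a control lentivirus or to a lentivirus labelled for overexpression (OE) of Ube2g1, and GFP-positive cells were sorted again after a further 24 h in fresh medium. Expression was measured by RNA sequencing in 4 groups of 4 libraries, named young control, young OE, aged control and aged OE. Total counts per library were 37390269 to 72692081 in young control, 57408316 to 78000939 in young OE, 31199413 to 101659592 in aged control and 38992872 to 93796932 in aged OE. The title of the series frames the question as whether raised Ube2g1 in stem cells leads to ageing of parts of the blood system.

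The young groups varied far more between libraries than the aged groups did. The biological coefficient of variation was 124% in young control and 131% in young OE, against 68.5% in aged control and 67.7% in aged OE. Between 15692 and 17281 genes were detected in young libraries 1 to 3 of either vector, 26130 in young control library 4 and 24683 in young OE library 4, and 17581 to 23343 in the aged libraries. The labels do not say that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be partly technical.

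Ube2g1, which encodes an E2 ubiquitin-conjugating enzyme, was not measurably higher in the libraries labelled OE. Its level in young cells was 116 ± 62.4 CPM (counts scaled to a common library total) with the OE vector (range 56.8 to 204) and 98.5 ± 41.6 with the control vector (range 63.6 to 158; SD, n = 4 each, exact two-sided permutation p = 0.657). In aged cells it was 125 ± 13.9 (range 113 to 143) against 109 ± 46.3 (range 46.3 to 145; exact permutation p = 0.714). The gene (ENSMUSG00000020794) lies on chromosome 11, positions 72607283 to 72686481 on the plus strand of GRCm38, and no other annotated exon overlaps its exons. The fitted log2 fold changes were 0.24 (SE 0.40, edgeR adjusted p = 0.934) in young and 0.20 (SE 0.40, adjusted p = 1.00) in aged cells. The smallest p that 4 against 4 libraries allow is 0.0286, and the 95% intervals allow a rise of up to 2.13-fold in young and 2.07-fold in aged cells. Without young OE library 2 the young value was −0.15, and without aged control library 3 the aged value was −0.11. Whether reads from the vector insert were counted at this gene is not given in the sources used here. The words OE and control below are the labels of the libraries, which the level of this gene did not bear out.

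**Figure D1:**
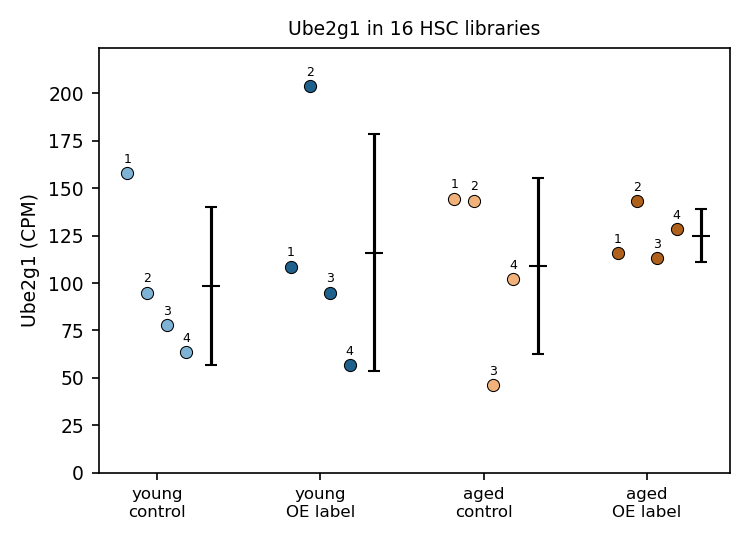
Ube2g1 level (CPM, vertical axis) in each of the 16 libraries, by group; points are libraries numbered as in the labels, and black marks with bars are the mean ± SD of 4 libraries. The OE and control libraries overlap at both ages, with means of 116 and 98.5 CPM in young and 125 and 109 CPM in aged cells.

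In young cells, megakaryocyte and platelet genes as a list stood higher, and granulocyte and mast cell genes lower, in the libraries labelled OE than in control libraries. At least the 5 lists that camera called here came from 29 of 35 splits of the young libraries, the real one included. Of 21 measured megakaryocyte and platelet genes, 19 had a log2 fold change above 0, with a median of 1.28 (camera adjusted p = 4.59e-06; adjusted p = 0.604 with an estimated correlation). Pf4, a platelet chemokine, stood at 2815 ± 4889 CPM against 255 ± 292 CPM (log2 fold change 3.47, SE 1.31, edgeR adjusted p = 0.467), and Cd9, a surface tetraspanin, had a log2 fold change of 1.75 (SE 0.57, adjusted p = 0.464). Of 19 myeloid and granulocyte genes, 14 lay below 0, with a median of −1.81, or −1.44 with the member at 0 in every library of a group set to its bound (camera adjusted p = 0.000585; adjusted p = 0.604 with an estimated correlation). The members chosen by abundance went little or not with the list, at −0.51 for Calr, an ER chaperone, and 0.14 for Cd63, a granule membrane protein. Among members picked after their values were seen, Lyz2, lysozyme of myeloid cells, had a log2 fold change of 2.16. Picked in the same way, Mpo, the myeloperoxidase of neutrophil granules, stood at 14.7 CPM against 2124 CPM (log2 fold change −7.17, SE 2.60, adjusted p = 0.466). Ctsg, a granule protease also picked afterwards, stood at 3.12 against 572 CPM (−7.52, SE 2.33, adjusted p = 0.464).

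Mast cell and basophil genes had a median of −3.21 in the same comparison, with 6 of 7 below 0 (camera adjusted p = 0.0385; adjusted p = 0.487 with an estimated correlation). The chemokine genes Ccl3 and Ccl4 had log2 fold changes of −3.47 and −3.21. G2/M and mitosis genes had a median of 0.34, with 24 of 26 above 0 (camera adjusted p = 4.15e-05; adjusted p = 0.604 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, stood at −0.38 and cyclin Ccnb1 at 0.20. All 15 mitochondrially encoded genes lay above 0, with a median of 0.56 (camera adjusted p = 0.000799; adjusted p = 0.960 with an estimated correlation), mt-Co1 at 0.43 and mt-Cytb at 0.83. The list of genes known to be higher in aged stem cells had a median of 0.58, or 0.52 with members at 0 in a group set to their bound, and did not pass (22 of 34 above 0, camera adjusted p = 0.107). Adjusted over the list alone, 1 of the mast cell and basophil genes and none of the genes in the other lists named for this comparison passed.

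No gene passed in young OE against young control by edgeR, where 1728 of 18313 genes had an unadjusted p under 0.05. DESeq2 called 504 genes (223 higher) and limma-voom called 0. The smallest p, which did not pass, belonged to Rpusd2, a predicted pseudouridine synthase, with a log2 fold change of −8.21 (SE 1.15; 0.0414 ± 0.0184 against 12.8 ± 12.0 CPM, edgeR adjusted p = 0.0673). The next with a proper symbol were the phosphatase gene Ppm1j, at 4.56 CPM against 0 in all control libraries and so at least 87.0-fold higher, and Ikbke, a kinase of innate immune signalling, at −8.18 (SE 1.46). Arhgap31, a Rho GTPase-activating protein, stood at −6.24 (SE 1.12) and Aspa, aspartoacylase, at 6.50 (SE 1.24), neither of which passed. The megakaryocyte score was 6.29 in young OE library 3 and 0.84 in young control library 3, and the myeloid score 1.24 and 6.42, the widest gaps of the 4 numbers. Without both libraries, an alternative added after these values were seen, the medians were 0.16 and −0.07 and neither list passed. Leaving out 1 library gave 4 genes without young control 1, 3 without young control 2, 2 without young OE 3 and 1 without young control 4. The 5 lists became 9 without young control 3, 3 without young control 2 or 4 and 2 without young OE 3.

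**Figure D2:**
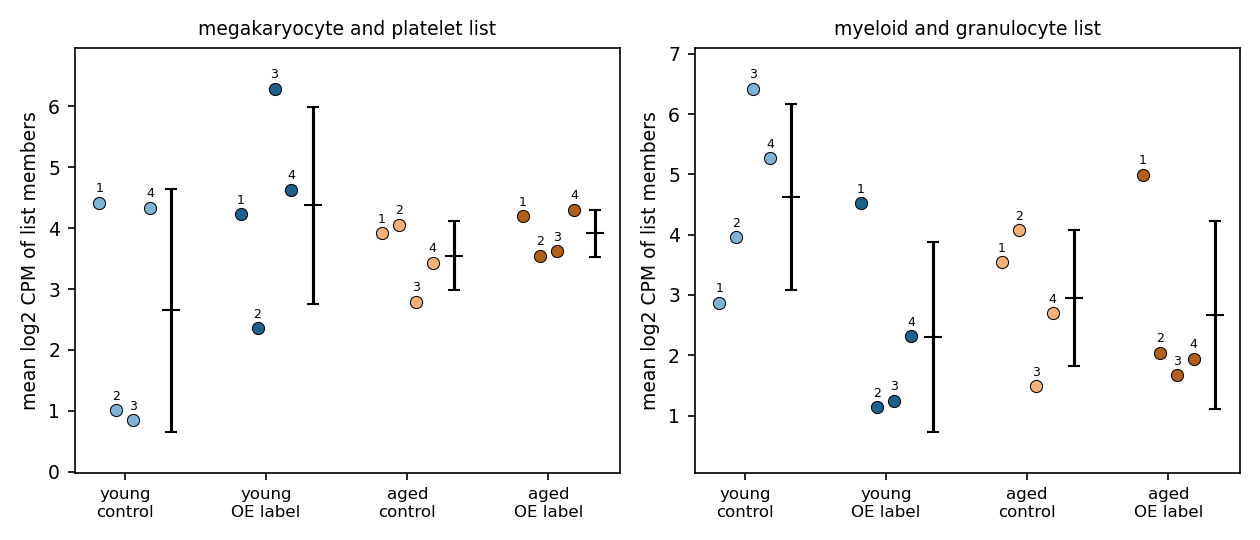
Mean log2 CPM of the measured megakaryocyte and platelet genes and of the myeloid and granulocyte genes (vertical axes) in each library, by group; points are libraries numbered as in the labels, and black marks with bars are the mean ± SD of 4 libraries. The young libraries spread from 0.84 to 6.29 in the megakaryocyte score and from 1.14 to 6.42 in the myeloid score.

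In aged cells camera called 7 lists between the libraries labelled OE and control, each with a small median shift, and none passed with an estimated correlation. At least as many lists came from 11 of 35 splits of the aged libraries, the real one included. Cytosolic ribosomal protein genes were lower as a list, with a median of −0.14 and 49 of 53 below 0 (camera adjusted p = 5.10e-12; adjusted p = 0.885 with an estimated correlation). The abundant Rplp0 and Rpl4 stood at −0.05 and 0.09, and Rps29 and Rpl38, picked after their values were seen, at −0.56 and −0.48. Oxidative phosphorylation genes had a median of −0.09 (30 of 42 below 0, camera adjusted p = 0.000155; adjusted p = 0.885 with an estimated correlation), although Atp5b, a subunit of ATP synthase, stood at 0.15. G1/S and DNA replication genes lay higher with a median of 0.17 (26 of 31 above 0, camera adjusted p = 0.000892; adjusted p = 0.885 with an estimated correlation), with Mcm6, a subunit of the replicative helicase, at 0.39 (SE 0.25). Genes of ER-associated degradation lay above 0 in 19 of 22 cases (median 0.21, camera adjusted p = 0.00884; adjusted p = 0.885 with an estimated correlation), with Vcp, the segregase that extracts ER proteins, at 0.24. ER chaperone and unfolded protein response genes did so in 17 of 20 (median 0.22, camera adjusted p = 0.0432; adjusted p = 0.885 with an estimated correlation), with Hspa5, the main ER chaperone, at 0.24. Heat shock and cytosolic chaperone genes did so in 20 of 24 (median 0.14, camera adjusted p = 0.0265; adjusted p = 0.885 with an estimated correlation), with Hspa8 at 0.15.

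Immediate early and handling stress genes had a median of −0.35 in aged OE against aged control (16 of 22 below 0, camera adjusted p = 0.0269; adjusted p = 0.885 with an estimated correlation), with the transcription factors Junb at −0.39 and Klf6 at 0.12. The HSC ageing list had a median of 0.13 and a mean of 0.02, while its camera test pointed lower (adjusted p = 0.662), and the myeloid list had a median of 0.10 with a test pointing lower (adjusted p = 0.734). Megakaryocyte genes had a median of 0.28 (adjusted p = 0.416) and interferon response genes of 0.27 (adjusted p = 0.0764). Adjusted over the list alone, no member of the lists named for this comparison passed.

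No gene passed in aged OE against aged control by edgeR (116 with an unadjusted p under 0.05), while DESeq2 called 18 (6 higher) and limma-voom 4, all lower. Fitted with only the aged groups, edgeR also called 0 (445 of 17427 genes with an unadjusted p under 0.05). Of genes with a proper symbol, the 5 with the smallest p had an edgeR adjusted p of 1.00; 5 unnamed gene models had smaller p. Among the 5 named, Uqcr10, a subunit of respiratory complex III, stood at 141 ± 17.6 against 197 ± 36.6 CPM (log2 fold change −0.48, SE 0.15) and Ccdc137 at 32.3 ± 5.72 against 19.3 ± 1.70 CPM (0.75, SE 0.25). Akap12, a kinase scaffold, Itgb1bp2 and Apol8 were at 0 in all aged OE libraries and so at least 6.49-fold, 24.6-fold and 15.5-fold lower. Their aged control levels were low and uneven, at 0.289 ± 0.264, 1.09 ± 1.19 and 0.690 ± 0.576 CPM, and for Akap12 the groups overlapped. The number of lists fell from 7 to 2 without aged control library 1, 3 without aged OE library 2 and 4 without aged control library 3.

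Averaged over both ages, camera called 6 lists between the libraries labelled OE and control, 5 of them also called in young cells and the ribosomal protein list in aged cells. At least as many came from 63 of 100 regroupings, the real one included. Megakaryocyte genes had a median of 0.82 (camera adjusted p = 4.90e-06; adjusted p = 0.792 with an estimated correlation). Myeloid genes had a median of −0.74 (0.00153; adjusted p = 0.884 with an estimated correlation) and mast cell genes of −1.41 (0.0462; adjusted p = 0.615 with an estimated correlation). G2/M genes had a median of 0.19 (0.0122), ribosomal protein genes of −0.11 (5.94e-05) and mitochondrially encoded genes of 0.34 (0.00169), each with adjusted p = 0.903 with an estimated correlation. The machinery around Ube2g1 did not pass: proteasome subunits had a median of −0.00 (camera adjusted p = 0.628) and ubiquitin E1, E2 and cullin-RING genes of 0.01 (0.595). HSC and stemness markers had a median of 0.12 (adjusted p = 0.745), polarity and Rho GTPase genes 0.04 (0.926), Polycomb, DNA methylation and chromatin genes 0.01 (0.595, the test pointing lower), and cytokine receptor and JAK-STAT targets 0.17 (0.595). NF-kB and inflammatory genes had a median of 0.00 (0.75), ATF4 and integrated stress response genes 0.14 (0.926) and autophagy and lysosome genes 0.09 (0.595, with a mean of −0.02). Cholesterol synthesis genes had a median of −0.08 (0.463). Markers of other cells that the sort could hold did not pass either: erythroid genes had a median of 0.39 (0.562) and mature B and T cell genes −0.62 (0.114). Monocyte and macrophage genes had a median of 0.61 (0.941, the test pointing lower) and endothelium and stroma genes 0.02 with a mean of −0.34 (0.941). Of the sex-linked genes, listed as a check of the labels, only Xist was measured, at 0.54 (0.462).

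By edgeR no gene passed in the average over both ages (1009 with an unadjusted p under 0.05; DESeq2 called 242 and limma-voom 0). The 5 genes with a proper symbol and the smallest p were Rpusd2 (log2 fold change −3.95, SE 0.67, edgeR adjusted p = 0.568), Ikbke (−4.42), Ppm1j (4.86), Zcchc3 (−6.32) and Fhl2 (−4.19), none of which passed. Leaving out young OE library 4 brought the number of lists from 6 to 3, and leaving out young control library 4 gave 1 gene.

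When the difference of the OE effect between the ages was itself tested, camera called 7 lists. At least as many came from 48 of 100 regroupings, the real one included. By edgeR no gene passed (904 with an unadjusted p under 0.05, smallest adjusted p = 0.286 for Rpusd2), while DESeq2 called 213 and limma-voom 0. The aged minus young difference had a median of −0.95 for megakaryocyte genes (camera adjusted p = 0.000936), 2.08 for myeloid genes (0.00529) and 3.59 for mast cell genes (0.0329). With an estimated correlation the adjusted p was 0.733 for the megakaryocyte and myeloid lists and 0.508 for the mast cell list. The difference was −0.42 for G2/M genes (8.63e-05), −0.17 for oxidative phosphorylation genes (0.0195), −0.42 for mitochondrially encoded genes (0.0329) and 0.13 for lymphoid priming genes (0.0405). With an estimated correlation the adjusted p was 0.733 for the G2/M and lymphoid lists and 0.895 for the oxidative phosphorylation and mitochondrial lists. Satb1, Dntt and Ighm, genes of early lymphocyte development, passed when adjusted over the lymphoid list alone. Without both young libraries numbered 3 the count was 1 list, and it was 3 without aged OE library 1 and 4 without young OE library 3; leaving out young OE 3 or young control 4 gave 1 gene.

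Single genes and the list fixed for stem cell ageing differed between aged and young cells. In cells with the control vector, Bmpr1a, a receptor for bone morphogenetic proteins, stood at 17.0 ± 4.61 CPM in aged and 0.155 ± 0.143 CPM in young libraries (SD, n = 4 each; log2 fold change 6.78, SE 0.98, edgeR adjusted p = 0.0374). The gene (ENSMUSG00000021796) lies on chromosome 14, 34410734 to 34503341 on the minus strand, where an antisense gene overlaps its exons. Sbspon, an extracellular matrix gene (ENSMUSG00000032719, chromosome 1, 15853862 to 15892722, minus strand), had 1440 counts in the aged and 1 count in the young libraries, a ratio of 1225 with a 95% counting interval of 220 to 48422. Nupr1, a stress-induced chromatin protein of the ageing and ATF4 lists (ENSMUSG00000030717, chromosome 7, 126623249 to 126630861, minus strand), stood at 95.3 ± 35.8 against 7.66 ± 2.04 CPM (3.64, SE 0.56). Lower in aged cells was Fcer1g, the signalling chain of Fc receptors, at 33.2 ± 4.96 against 196 ± 103 CPM (−2.57, SE 0.39; ENSMUSG00000058715, chromosome 1, 171229572 to 171234365). Trf, transferrin, stood at 49.5 ± 10.3 against 170 ± 25.8 CPM (−1.78, SE 0.26; ENSMUSG00000032554, chromosome 9, 103204001 to 103230444). Adgrg3, an adhesion G protein-coupled receptor, stood at 80.0 ± 16.0 against 232 ± 17.0 CPM (−1.53, SE 0.24; ENSMUSG00000060470, chromosome 8, 95017692 to 95045250).

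These 6 genes and Car5b, a mitochondrial carbonic anhydrase named after its values were seen because it was too low for the rule (662 counts against 1, ratio 563, interval 101 to 22279), made up the calls by edgeR in aged against young control. Of these, 4 were higher and 3 lower (1773 genes had an unadjusted p under 0.05), each with an adjusted p of 0.0374 and with all aged libraries beyond all young ones. DESeq2 called 518 genes (391 higher), where it called 397 unchanged genes in simulated counts, and limma-voom 39 (26 higher). Fitted with only these 2 groups, edgeR called 0, and with the number of detected genes as a covariate 1. In all, 1403 of 18313 genes (7.66%) had no overlap between the 4 aged and 4 young control libraries, where chance gives 2.86% for groups of equal spread. The wider spread of the young libraries can raise that share without any change, so the excess is not told from the uneven spread. Leaving out any 1 of 7 of the 8 libraries (each aged control library and young control 2, 3 or 4) ended all calls by edgeR. Without young control 1, 8 genes passed, of which 3 were among the 7 calls. Intervals and floors here cover counting error only, since the reads carry no molecular identifiers.

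The list of genes known to be higher in aged stem cells had a median log2 fold change of 2.07 in the control vector, with 29 of 34 members above 0 (camera adjusted p = 3.37e-17; adjusted p = 0.0249 with an estimated correlation). Besides Sbspon and Nupr1, which passed over all genes, 9 more passed when adjusted over the list alone, 11 in all. ER chaperone and unfolded protein response genes lay lower, with a median of −0.39 and 17 of 20 below 0 (camera adjusted p = 2.07e-05; adjusted p = 0.396 with an estimated correlation), 3 of them passing when adjusted over the list alone. Among them Hspa5 stood at 737 ± 119 against 1210 ± 367 CPM (−0.71, SE 0.22, edgeR adjusted p = 0.312), and Pdia3, a disulphide isomerase, at −0.10. Heat shock and cytosolic chaperone genes had a median of −0.24 (21 of 24 below 0, camera adjusted p = 0.000298) and ER-associated degradation genes of −0.32 (16 of 22 below 0, 0.0133), both with an adjusted p of 0.378 with an estimated correlation.

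The myeloid and lymphoid priming lists were lower in aged than in young control cells, while the erythroid, megakaryocyte and monocyte lists were not called. Myeloid and granulocyte genes had a median of −2.48 (14 of 19 below 0, camera adjusted p = 0.00108; adjusted p = 0.519 with an estimated correlation) and lymphoid priming genes of −1.02 (10 of 14 below 0, 0.00126; adjusted p = 0.378 with an estimated correlation). The abundant members did not follow throughout, with Cd63 at 0.61, Calr at −0.97, Lsp1, an actin-binding protein of leukocytes, at 0.88 and Mef2c, a transcription factor, at −0.60. Flt3, the receptor of lymphoid progenitors picked after its value was seen, stood at 9.97 against 44.0 CPM (log2 fold change −2.14, adjusted p = 0.391). G1/S genes had a median of −0.17 (camera adjusted p = 0.00631; adjusted p = 0.572 with an estimated correlation), with Cdk4 at −0.17. Glycolysis and hypoxia genes had a median of −0.18 (0.0129; adjusted p = 0.530 with an estimated correlation), with Ldha at −0.36, and ribosomal protein genes of −0.12 (43 of 53 below 0, 0.000508; adjusted p = 0.813 with an estimated correlation). In 20 simulations with no change but the wider spread of the young libraries, camera called 6.95 lists on average in this comparison, and 4.85 with an estimated correlation. The ageing list was among them in 10 and 9 of the 20, so neither p alone tells it from the uneven spread, and its simulated median was at most 0.74. The observed 2.07 lies outside that range, as do the medians of the myeloid (simulated −0.38 to 0.29), lymphoid priming (−0.76 to 0.38) and ER chaperone lists (−0.28 to 0.03). Those of the other 5 lists called lie inside their simulated ranges. The simulated genes vary independently of each other, so genes that vary together could give wider ranges. Splits of the young libraries alone, with no difference in age, gave absolute medians of the ageing list of up to 1.38. Between the young vectors the myeloid median was −1.81, also outside the range simulated here, so that range does not set the myeloid list apart.

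**Figure D3:**
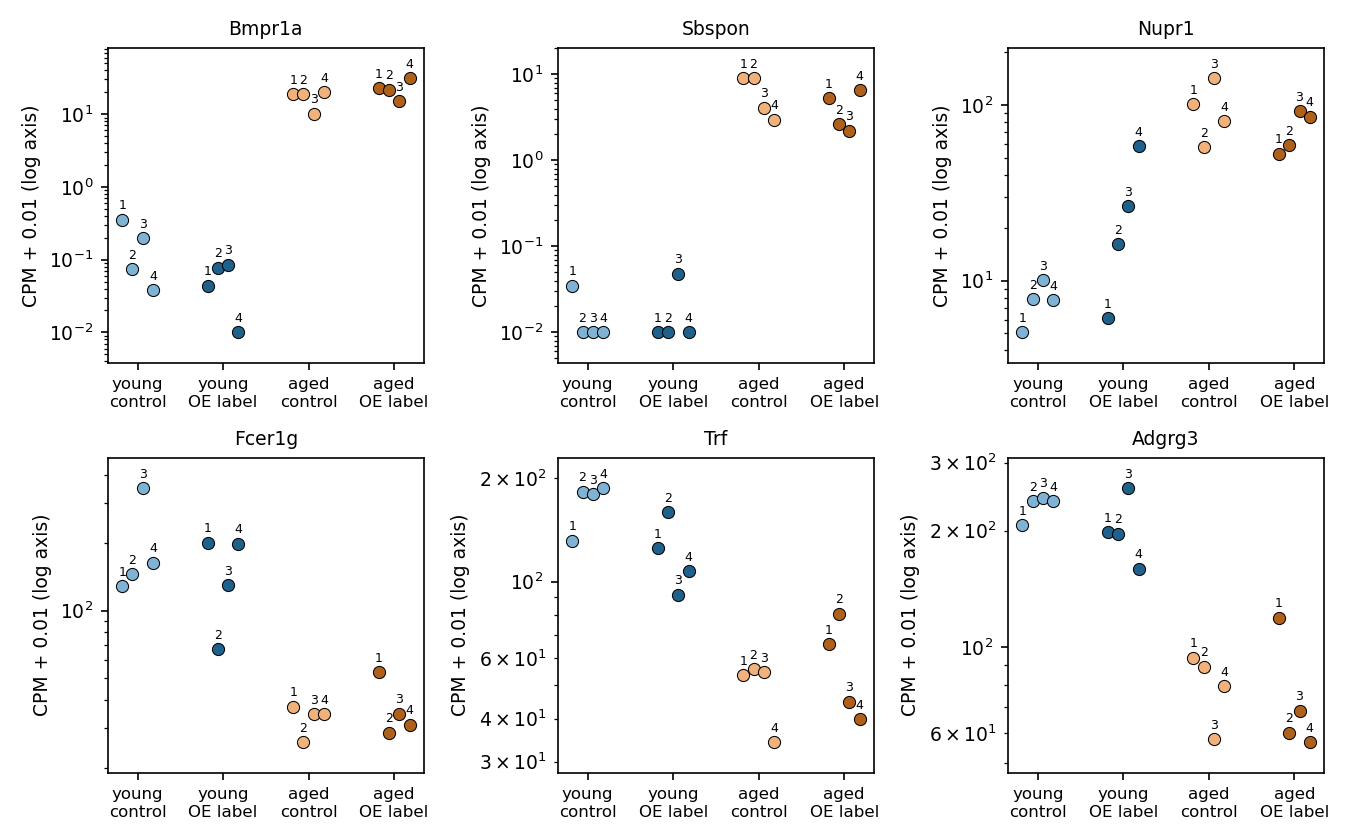
Level of 6 genes in each library by group, on a log axis of CPM with 0.01 added; points are libraries numbered as in the labels. Bmpr1a, Sbspon and Nupr1 lie higher in every aged control library than in any young control library, and Fcer1g, Trf and Adgrg3 lower.

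With the OE vector, aged cells again held more Bmpr1a, at 22.6 ± 6.59 against 0.0444 ± 0.0345 CPM (SD, n = 4 each; log2 fold change 8.97, SE 1.08, edgeR adjusted p = 0.0110). It was the only call of edgeR in this comparison, where 1825 genes had an unadjusted p under 0.05. DESeq2 called 625, of which 497 higher (405 unchanged genes in simulated counts), and limma-voom 24, of which 16 higher. Fitted with only these 2 groups, edgeR called 0 (smallest adjusted p = 0.0812). Not passing, with the next smallest p among genes with a proper symbol, were Fetub, a fetuin, at 3.14 CPM against 0 in all young OE libraries and so at least 63.5-fold higher (adjusted p = 0.0509), and Tc2n, at least 94.5-fold higher (0.0509). Gpr183, an oxysterol receptor of the ageing list, was at least 71.3-fold higher (0.0591), and Rpusd2 had a log2 fold change of 7.25 (SE 1.11, 0.0509). Sbspon had 1372 counts against 2, a ratio of 551 with an interval of 152 to 4556 (adjusted p = 0.0591). Without young OE library 1 no gene passed, and without aged OE 1, young OE 2 and young OE 4 the counts were 2, 2 and 3. Groups without overlap were seen for 1388 genes (7.58%, where chance gives 2.86% for groups of equal spread), an excess that the uneven spread could also give.

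The ageing list had a median of 1.48 with the OE vector, with 27 of 34 above 0 (camera adjusted p = 2.71e-10; adjusted p = 0.147 with an estimated correlation), with no member passing over all genes and 12 adjusted over the list alone. Its abundant members Cd9 and Mt1, a metallothionein, stood at −0.61 and 0.86. G2/M and mitosis genes lay lower in all 26 members, with a median of −0.48 (2.95e-09; adjusted p = 0.395 with an estimated correlation), and Ccnb1 at −0.13. Interferon response genes had a median of 0.79 (26 of 35 above 0, 0.000715) and p53 targets and senescence genes of 0.59 (17 of 23 above 0, 0.0323), both with adjusted p = 0.602 with an estimated correlation. Ccng1, a p53 target, stood at 327 ± 73.4 against 125 ± 44.9 CPM (1.39, SE 0.47, edgeR adjusted p = 0.313). Log2 fold changes were 0.36 for Bax, 0.63 for Lgals3bp and −0.26 for Ifitm3. Megakaryocyte genes had a median of −0.92 (17 of 21 below 0, 0.00545) and ER chaperones of −0.35 (18 of 20 below 0, 0.000149), both with adjusted p = 0.602 with an estimated correlation, and Pf4 stood at −3.90. Heat shock genes had a median of −0.11 (0.0475), oxidative phosphorylation genes of −0.16 (33 of 42 below 0, 1.69e-05) and ribosomal protein genes of −0.22 (51 of 53 below 0, 2.08e-09), each with adjusted p = 0.602 with an estimated correlation. In the simulations with no change camera called 6.75 lists on average here (4.25 with an estimated correlation), and the ageing list in 8 of 20 (5 with an estimated correlation), with a median of at most 0.48. Simulated genes vary independently of each other, so that bound can be too low. Splits of the young libraries alone, with no difference in age, gave absolute medians of this list of up to 1.38.

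**Figure D4:**
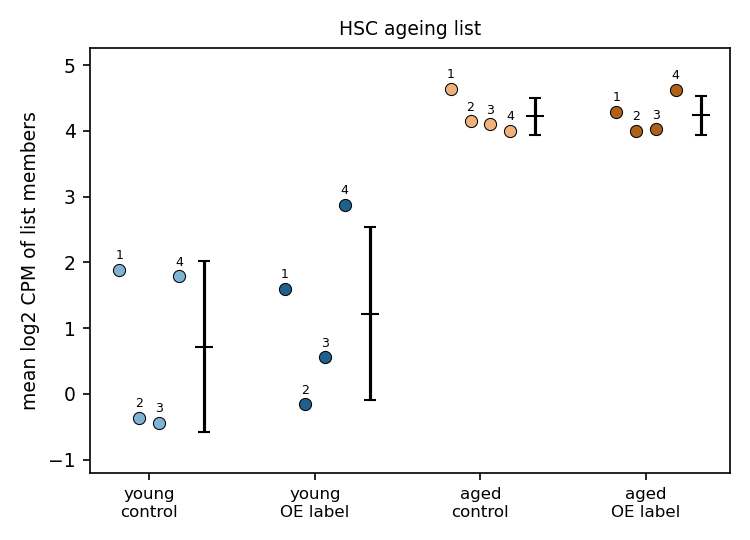
Mean log2 CPM of the 34 measured genes of the stem cell ageing list (vertical axis) in each library, by group; points are libraries numbered as in the labels, and black marks with bars are the mean ± SD of 4 libraries. The 8 aged libraries lie between 4.0 and 4.64, above the 8 young libraries of either vector, which reach 2.87.

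The change labelled OE in young cells was set against the change with age, because the series asks whether Ube2g1 moves young cells towards the aged state. Across the 18313 genes tested, which are not independent replicates, the young OE changes correlated with the aged minus young control changes at r = 0.487 (covariance 1.95). Both comparisons use the young control libraries, and 20 simulations with no change gave r = 0.618 on average (0.604 to 0.631; covariance 2.05). With the young controls split into 2 and 2, r averaged 0.0652 over 6 splits (range −0.00233 to 0.132) and the covariance 0.409, against 0.0805 (0.0666 to 0.105) and 0.479 without any effect. Both observed r lay below all 20 simulated values. The observed minus simulated covariance was −0.0964 and −0.0700 (SD of the simulated value 0.0491 and 0.0517), so no shared change in the same direction was seen above the simulated value. The simulated libraries vary independently; control and OE libraries that vary together would lower the value to compare with, so a shared change is not excluded. The unsplit r was 0.295 without young OE library 4 and 0.676 without young control library 4. In the self-test a planted covariance of 0.587 was recovered as 0.647 above the value without it. The OE changes of young and aged cells, which share no library, correlated at r = −0.00278 across genes (−0.00916 simulated with no change), and 0 calls were shared where 0 were called. At a mean of 10 CPM or more r was −0.109, against −0.0380 to 0.0228 in 20 simulations in which genes and libraries vary independently.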

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

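The tests of the young libraries in the last paragraph, except leaving out each library in turn, were chosen after the result was seen, and the regroupings of the libraries were set before it.

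When the difference of the OE effect between young and aged cells was itself tested, camera called 7 gene lists. The camera adjusted p of the difference was 0.000936 for megakaryocyte genes, 0.00529 for myeloid genes, 0.0329 for mast cell genes and 0.0405 for lymphoid priming genes. It was 8.63e-05 for G2/M genes, 0.0195 for oxidative phosphorylation genes and 0.0329 for mitochondrially encoded genes, and none passed with an estimated correlation (lowest adjusted p = 0.508). Of 100 regroupings of the libraries, the real one included, 48 gave at least the 7 lists of the real one (highest other 17), so chance is not excluded for that count. Any regrouping gives at least the real 0 genes (100 of 100, highest other 65), which says nothing about chance.

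The counts of lists for OE against control also stayed within what other groupings gave; the counts of genes were 0, which any grouping matches, so they say nothing about chance. Of the 35 splits of the young libraries into 4 and 4, 29 gave at least the real 5 lists (highest other 15) and 35 at least 0 genes (highest other 203). The split with 203 genes set both libraries numbered 1 and both numbered 4 against the rest; the next gave 113 and 57 and part some of the numbers, and the other two that keep the numbers together gave 35 (1 and 3 against 2 and 4) and 3 (1 and 2 against 3 and 4). Counts that large point to a structure of the young libraries that the groups do not follow. The splits exchange libraries as if unpaired. DESeq2 called 504 genes in the real split and 465 to 2062 in the others, with 33 of 35 at least as many. In aged cells 11 of 35 splits gave at least the real 7 lists (highest other 10) and 35 at least 0 genes (highest other 0). For the average over both ages, 63 of 100 regroupings gave at least the real 6 lists (highest other 13) and 100 at least 0 genes (highest other 41), so chance is not excluded for any of these counts of lists.

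In 11 of 144 groups of 4 values, 1 library stood so far from the rest that its gap to the nearest, as a share of the group's range, was above the 95% critical value of Dixon's test. Chance flags about 1 in 20 groups. For genes detected the share was 0.891 in young control (26130 in library 4 against 15692 to 16833), 0.849 in young OE (24683 in library 4 against 15962 to 17281) and 0.892 in aged OE (17581 in library 2 against 22127 to 22677). Young OE library 3 stood apart in 5 list scores. These were ER-associated degradation at 6.51 against 5.96 to 6.0 (share 0.941), ER chaperones at 7.70 against 7.03 to 7.13 (0.847) and autophagy and lysosome at 5.29 against 6.35 to 6.44 (0.916). In p53 targets it stood at 2.67 against 4.02 to 4.08 (0.954) and in Xist at 7.77 against 5.47 to 5.81 (0.853). The myeloid score of aged OE library 1 was 4.99 against 1.67 to 2.04 (0.889). The mast cell score of young control library 4 was 1.72 against 0.22 to 0.40 (0.881), and the cytokine receptor and JAK-STAT score of aged OE library 2 was 2.56 against 4.16 to 4.46 (0.841).

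Megakaryocyte genes lay higher and myeloid genes lower in young OE than in young control libraries, and both shifts may rest on a few libraries, which the values neither show nor exclude. Without both young libraries numbered 3 the camera adjusted p of the megakaryocyte list was 0.221, but these were left out because their scores lay widest apart, so the loss decides nothing. By values looked up afterwards, both also stood apart in other ways. Their median correlations with the other libraries were the lowest, at 0.795 (control) and 0.782 (OE), with 0.833 the next. Their HSC and stemness scores were 1.36 and 1.47, against 3.15 to 5.30 in the other young libraries. With each young library left out in turn, the megakaryocyte list passed in 7 of 8 fits and had an adjusted p of 0.0642 without young OE library 3 (median 0.41 against 1.28). The myeloid score ranged over 3.55 log2 units within young control alone, against 2.32 between the group means, but a range of single scores exceeds a difference of means too easily to decide whether libraries of mixed lineage gave the difference. An effect of the vector stays open, because the megakaryocyte scores of the 4 and 4 libraries gave an exact permutation p of 0.229, which neither shows nor excludes it.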

How the results depend on the processing

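The fits without both young libraries numbered 3, thinned to the smallest library, with date cells as 0 and with detected genes as a covariate were chosen after the results were seen, as was the averaged comparison of age. Counts below are in the order OE in young cells, OE in aged cells, age with the control vector, age with the OE vector, difference between ages, OE averaged and age averaged. The main counts were 0, 0, 7, 1, 0, 0 and 266 genes and 5, 7, 9, 9, 7, 6 and 11 lists. Where a count moved, the cause was not tested, except that fewer libraries or genes enter some fits by construction. Of 158 counts of genes under alternatives 61 moved by over 1.5 times, as did 27 of 122 counts of lists. The 8 calls of single genes for age with either vector kept their direction in 152 of 152 cases and lost the threshold in 83; those of age averaged were not followed singly. Those of single lists kept it in 948 of 948 and lost the threshold in 237. The ageing list held its call in 14 of 14 alternatives with the control vector, 13 of 14 with the OE vector and 22 of 22 averaged. After thinning to the smallest library (31199413 counts) 16853 genes in place of 18313 were tested, and edgeR called 13 and 3 genes for age with the control and OE vector, 258 for age averaged and 0 in the other 4 comparisons.

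With an estimated correlation camera called 0, 0, 1, 0, 0, 0 and 1 lists, and fry 0, 0, 1, 1, 0, 0 and 5. DESeq2 called 504, 18, 518, 625, 213, 242 and 1371 genes and limma-voom 0, 4, 39, 24, 0, 0 and 696. RLE scaling gave 4 genes for age with the OE vector. Without a filter there were 1 for OE in young cells, 4 for age with the control vector and 169 for age averaged, and with the stricter filter 14 and 14 for the age comparisons. Fits of only the groups compared gave 0 and 0 there. Without both young libraries numbered 3 the genes were 4 for OE in young cells, 14 and 12 for age with either vector and 3 for the difference. The lists were 1 for OE in young cells, 1 for the difference and 1 for OE averaged. Date cells as 0 gave 5 for age with the OE vector. The covariate gave 1 for OE in young cells, 1 and 2 for age with the control and OE vector and 203 for age averaged. At a mean of 10 CPM or more the correlation of the OE effect between ages was −0.109, and with young controls split that of young OE with age was 0.0652.

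Replicate numbers were taken to pair the libraries only where every same-numbered pair deviated together at r over 0.1. Young control and OE pairs had r of 0.0476 to 0.221 and aged pairs 0.0891 to 0.311, so 1 pair in each age missed that bound. Yet each of the 8 control libraries correlated best with the OE library of its own number, and other aged pairs reached at most 0.0793. Young OE 1 correlated more with young control 4, at 0.0567. These values point towards pairing, but the labels do not say what a number stands for, so it stays open. The main list tests and the permutation tests between vectors took the libraries as unpaired. No list was tested with the number as a block within each age. With the replicate number as a block edgeR called 0 genes for age with the control vector and 0 with the OE vector. For age averaged it called 197, of which 154 were among the main 266. With the block within each age it called 0 genes in each of the 4 comparisons of vectors, as without it.

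Leaving out 1 library at a time gave 0 to 4 genes for OE in young cells, 0 to 8 and 0 to 3 for age with the control and OE vector, 0 to 1 for the difference, 0 to 1 for OE averaged and 82 to 406 for age averaged. Lists ranged over 2 to 9, 2 to 8, 7 to 13, 8 to 12, 3 to 10, 3 to 8 and 9 to 15 in the order above. The Ube2g1 log2 change ranged from −0.15 (without young OE 2) to 0.56 in young cells and from −0.11 (without aged control 3) to 0.33 in aged cells. The correlation of young OE with age ranged from 0.295 to 0.676 and that of the OE effect between ages from −0.022 to 0.021.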

Other observations

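The comparison of age averaged over both vectors, the tests of abundant members and of scores without logs, and the technical readings of the Ube2g1 level were chosen after the results of the other comparisons were seen; the covariate test and the regroupings were set before their results.

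With both vectors averaged, 8 aged against 8 young libraries, single genes differed in both directions. By edgeR 210 genes passed as higher and 56 as lower (2703 with an unadjusted p under 0.05; DESeq2 called 1371, of which 965 higher, and limma-voom 696, of which 530 higher). Under the rule for named genes, with its minimum of 5 CPM, the higher ones were Sbspon, with 2812 against 3 counts (ratio 774, 95% counting interval 265 to 3757), and Cd38, an ectoenzyme that degrades NAD (log2 fold change 7.91, SE 1.22, adjusted p = 0.00646). The others were Bmpr1a (7.87, SE 0.73, 0.000373), the adhesion molecule Cadm1 (6.73, 0.0225), Scrn1 (7.37, 0.0288), Wfdc2 (7.13, 0.0217), Gipc2 (6.28, 0.0103) and Emp2 (6.24, 0.0153). Lower were Engase, an enzyme that trims N-glycans (−2.61, SE 0.37, 0.00388), Fcer1g (−2.29, SE 0.27, 0.00122), the leukocyte tetraspanin Cd37 (−1.72, 0.0116) and Adgrg3 (−1.47, 0.00122). Further lower ones were lamin Lmnb2 (−1.44, 0.0141), Trf (−1.42, 0.00282), Bin1 (−1.37, 0.00388) and Fpgs (−1.32, 0.0336). Wipf3, Tead2 and Eng overlap the exons of Scrn1, Cd37 and Fpgs, so reads of those pairs cannot be told apart. Leaving out young OE 4 gave 406 genes. The main 266 became 82 without aged OE 4, 86 without aged control 1, 89 without aged control 4, 102 without aged OE 3, 121 without aged OE 1 and 131 without young OE 1. They became 151 without aged control 3, 154 without young control 3, 158 without aged control 2, 173 without aged OE 2 and 177 without young control 1. Simulations with no change but the wider spread of young libraries gave 33.95 genes on average and at most 62, with 32.9 on average higher in aged cells. Of 100 regroupings only 1, the real one, gave as many as 266 (highest other 2). The regroupings mix young and aged libraries and lose the uneven spread, which the simulations keep. Both stayed below 266, which argues against chance for the count, though simulated genes vary independently of each other. With the number of detected genes as a covariate 203 genes passed, of which 147 were among the 266. A loss of low genes from the young libraries was not tested for these calls and stays open.

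The ageing list was higher in the averaged comparison, with a median of 1.54 and 29 of 34 above 0 (camera adjusted p = 1.04e-17; adjusted p = 0.0228 with an estimated correlation). Of its members 10 passed over all genes and 17 adjusted over the list alone, of which 16 were higher and Jun lower. The 4 with the smallest p were Sbspon, Gpr183, which was at 0 in all young libraries and at 2.36 and 3.52 CPM in aged control and aged OE, Nupr1 (2.54, SE 0.38, 0.00526) and Trpc1, a cation channel (8.69, 0.0104). ER chaperone genes lay lower (median −0.34, 17 of 20 below 0, 1.54e-06; adjusted p = 0.465 with an estimated correlation). Sec61a1, the ER protein channel, passed as lower (−1.06, SE 0.25, edgeR adjusted p = 0.0480), and 5 passed when adjusted over the list alone. Interferon response genes had a median of 0.68 (29 of 35 above 0, 0.00158; adjusted p = 0.524 with an estimated correlation), with no member passing. Cholesterol synthesis genes did not pass as a list (median 0.00, 0.213), but Fdft1, squalene synthase, whose exons overlap those of Ctsb, and Sc5d passed as higher (0.68, SE 0.12, 0.0135 and 0.77, SE 0.17, 0.0413), and 5 passed when adjusted over the list alone. Lower lists were G2/M (median −0.32, 8.48e-05), heat shock (−0.17, 0.000666), ER-associated degradation (−0.22, 0.0409) and lymphoid priming genes (−0.83, 0.0165), each with adjusted p = 0.465 with an estimated correlation. Myeloid (−1.10, 0.0368), G1/S (−0.07, 0.0194), oxidative phosphorylation (−0.09, 0.00147) and ribosomal protein genes (−0.17, 2.48e-08) were lower too, each with adjusted p = 0.524 with an estimated correlation. In the simulations with no change camera called 10.6 lists on average here (8.35 with an estimated correlation, the ageing list in 15 of 20), so the 11 lists called are no more than the uneven spread gives, and 20 of 100 regroupings gave at least 11 (highest other 14).

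The rise of the ageing list in aged cells may be a property of the cells or of their libraries. With the number of detected genes as a covariate the adjusted p with an estimated correlation was 0.0319 averaged, which alone decides nothing. Scores without logs and without their trend on detected genes were −0.14 to 0.60 in aged and −0.98 to −0.04 in young libraries, which overlap. Their exact permutation p was 0.000777 with 8 libraries on each side taken as independent, which argues to that extent against detection as the whole cause. The 18 members with a mean of at least 20 CPM over all libraries had a median of 1.22 with the control vector, 16 of them above 0. With the OE vector it was 0.79, with 12 of 18 above 0. A member can reach that mean through the aged libraries alone, which favours a positive median, so a loss of low genes stays open for both vectors. Scores computed without logs, which the spread of low values moves less, were 1.10 to 1.75 in aged and 0.256 to 1.02 in young libraries. The exact permutation p was 0.000155 (n = 8 each, the smallest that 8 against 8 can give), which argues against the wider spread of young libraries as the cause. Both permutation tests took the control and OE libraries of an age as independent. If same-numbered libraries share a source, which stays open, 4 sets against 4 allow no p below 0.0286. Age itself and an unrecorded difference in handling by age stay open, untested.

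The results for age were also weighed against chance. The p of the ageing list with an estimated correlation was as small in 1 of 35 splits with the control vector (real 0.000778, smallest other 0.0350), 1 of 35 with the OE vector (0.00459 and 0.0625) and 1 of 100 averaged (0.000714 and 0.0246). A share of 1 in 35 is the smallest these splits can give. The other groupings mix young and aged libraries and lose the uneven spread, under which simulations with no change often called this list. The shares thus argue against a random grouping, but not against the uneven spread. For single genes with the control vector 1 of 35 splits gave as many as 7 (highest other 0), and simulations with no change gave at most 4. With the OE vector 3 of 35 gave at least 1 gene (highest other 1) and the simulations at most 6, so chance is not excluded there. For lists, 14 of 35 splits gave at least 9 with the control vector (highest other 15) and 19 of 35 at least 9 with the OE vector (highest other 15), so chance is not excluded for these counts.

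Ube2g1 was not raised in the libraries labelled OE, and 3 technical readings of this were set against the counts. Too few counts is argued against, since no library had fewer than 4202 counts at the gene. A transgene whose reads are not counted at the native gene could leave the count as it was: the highest fitted fold was 1.18, and no value decides this, because the sequence of the insert was not used here. A rise too small for 4 against 4 libraries also stays open, as the lower of both upper bounds was 2.07-fold. Whether protein was raised was not measured here.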
